A study of Staphylococcus aureus with 2 samples.

How the data were processed

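The series holds 2 RNA sequencing libraries of S. aureus T23, 1 without V12CBD and 1 with 25 µg/ml V12CBD, both after 4 h at 37 °C. Per the labels' protocols, total RNA was isolated with a column kit for bacteria, libraries were made with an Illumina TruSeq RNA kit and sequenced on a NextSeq. The labels do not state whether the kit marked the strand or whether rRNA was removed. The aligner, the program that counted reads and its version are not given in the sources used here.

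The authors deposited 1 table of features on the chromosome of a reference strain (gene coordinates as in assembly ASM1342v1), each with coordinates, strand and 4 values per library. It lists 2767 protein-coding genes, 441 predicted antisense RNAs, 28 predicted RNAs that name no gene, 16 rRNA genes and 61 tRNA genes. T23 is another strain than this reference, so genes of T23 that the reference lacks are not in the table. Raw counts in the deposited table were estimated counts with the decimals removed: dividing the normalised value by 1 constant per library returned the raw count as its whole part for 99.9% of features. An entry of 0 therefore means less than 1 estimated read. Normalised counts, a signal on the authors' own scale, were the estimated counts multiplied by 4979 without and 3382 with V12CBD. The rule for these constants is not given in the sources used here; their ratio was 1.47, while the reads assigned to all features had a ratio of 1.07. Expression, a score rounded to whole numbers by the authors, was the normalised count per base of feature length, per the values deposited. RPKM values were deposited as whole numbers, so they were treated as a rounded score and used as an alternative only. The deposited p-values and q-values are the authors' own comparison of the 2 libraries, and its test is not given in the sources used here; they are quoted as the authors' and never as a test of the conditions.

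With 1 library per group, no test between conditions was possible and no p-value was computed. The log2 ratio of normalised expression, with over without V12CBD, was taken after adding a pseudocount of 1, which understates the ratio of low genes. A gene was called higher or lower by size only, at a 2-fold difference, among protein-coding genes with a mean expression of 10 or more. Each ratio has a 95% counting interval (exact binomial, given the sum of both read counts, on the authors' scale), and each share of reads a Wilson interval. The intervals take the deposited counts as cut to whole numbers, so at a few reads they are approximate. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules, and they say nothing of the spread between cultures. In 1 alternative, genes with 0 reads in a library were set at a bound, computed against a floor of 3 counts per library.

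Lists of genes (42) were fixed before the data were examined, and their members were then identified from gene names and products alone. Lists with 3 or more members above the expression floor were compared with 10000 random lists of the same size, matched on mean expression in 10 bins, with a fixed seed. The percentile of a list's median among them describes these 2 libraries. Genes named in the text followed a rule fixed before the data were examined: the 12 highest and 12 lowest ratios among genes with a mean expression of 50 or more, up to 4 members per list with the largest absolute ratio, and 25 fixed virulence and cell wall genes. Exceptions are marked in the text. Symbols came from the table and from a reference table of assembly ASM1342v1, in which 2844 locus tags matched and 2766 of 2767 protein-coding genes had the same coordinates.

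Predicted antisense RNAs were assigned to a list where all genes they name belong to it, a comparison chosen after the data were seen because these RNAs held most reads. Their ratios are also given relative to their own class median. The share of reads in the 3 most read features was 39.9% without and 35.3% with V12CBD. Predicted RNAs that name no gene, rRNA and tRNA genes stayed out of gene counts, with the reads of rRNA genes at 0.0959% and 0.0726%. Alternatives were other scalings, pseudocounts, floors and size rules, raw counts (CPM) or RPKM as the value, unmatched random lists, lists without their most extreme member and adjacent members as 1 unit.

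The procedure was tested on simulated data drawn from the 2767 protein-coding genes. Of 500 random lists of 12 genes without any difference, 5.60% lay outside the central range, and all 200 lists made 2-fold higher lay above it. Both outcomes were largely set by the design. Null lists came from the same genes as the random lists, and the 2-fold change was added after the noise. Genes were drawn independently, so lists of neighbouring genes were not tested. The 2-fold rule recovered 90.0% of 200 genes made 4-fold different, and all 54 of them with 50 reads or more. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.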

Results

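RNA was sequenced from cultures of Staphylococcus aureus strain T23 kept for 4 h at 37 °C either without V12CBD or with 25 µg/ml of it. V12CBD is a protein derived from the cell wall-binding domain of a bacteriophage lysin, and the comparison asks which RNAs differed in level between the cultures. Each group had 1 library, so no difference had a replicate check and none was tested. The deposited table assigned 9061597 reads to annotated genes and predicted RNAs without V12CBD and 9698744 reads with it. Few of these reads lay on the annotated strand of a gene. Protein-coding genes received 137787 reads without V12CBD, or 1.52% of the library (95% Wilson interval 1.51% to 1.53%), and 183669 reads with it, or 1.89% (1.89% to 1.90%). A median gene had 8 and 12 reads. Predicted RNAs opposite annotated genes held 87.8% and 87.5% of the reads, and 28 predicted RNAs that name no gene held 10.5% in both libraries. Gene values below are from the annotated strand unless an antisense RNA is named. Whether the strand of messenger RNA was assigned in reverse stays open. If it was, the gene values would come from the strand opposite the messenger RNA, and the antisense values would be the deeper measure of these genes. How reads were assigned to a strand is not stated, so a gene and its antisense partner cannot be fully separated, and intervals cover counting error only, on counts cut to whole numbers.

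The listed genes for proteins anchored in the cell wall were lower in the library with V12CBD. They encode protein A, the fibronectin-binding proteins, the clumping factors and the Sdr proteins, a part of this class. All 7 measured members of this list lay below the median of annotated genes, and 4 were at least 2-fold lower, of which protein A and the clumping factor lie at the threshold. Protein A (SAOUHSC_00069, at 73429 to 74979 on the minus strand), which binds the Fc part of immunoglobulin G, had 14579 reads without and 10686 reads with V12CBD. Its normalised expression was 46802 against 23300, a log2 ratio of -1.01 with a 95% counting interval of -1.04 to -0.97. The fibronectin-binding protein SAOUHSC_02803 had 559 and 316 reads (log2 ratio -1.38, interval -1.58 to -1.18). The fibrinogen-binding protein SdrC (SAOUHSC_00544) had 107 and 65 reads (-1.26, -1.74 to -0.82). The clumping factor SAOUHSC_00812, a fibrinogen-binding adhesin, had 282 and 208 reads (-1.0, -1.26 to -0.73). The other members were fibronectin binding protein B (SAOUHSC_02802) at -0.89, SdrD (SAOUHSC_00545) at -0.78 and clumping factor B (SAOUHSC_02963) at -0.48. SdrD and clumping factor B lay outside the naming rule and were added after their values were seen. Locus tags drafted for the list were left out where the annotation names only a hypothetical protein. Among them, SAOUHSC_02798 had 5513 and 4714 reads (-0.78). SAOUHSC_02982 was not lower, with 27 and 40 reads (0.01 on normalised counts). SAOUHSC_02798 and SAOUHSC_02982 were also added after their values were seen. The drafted tags SAOUHSC_01873 and SAOUHSC_02990 are not in the list either, and their values are not given here. The list median was -1.0, or -1.05 relative to the median of all annotated genes. The central 95% of 10000 random lists of like expression ran from -0.48 to 0.43 in unadjusted medians, and no random list had so low a median. Equal totals over all features moved each log2 ratio up by 0.46, which left those 4 members short of 2-fold lower. The list median was then -0.54, or -1.04 relative to the median of genes. The clumping factors and Sdr proteins share repeat sequence, so reads between them may have been split in an uncertain way.

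**Figure D1:**
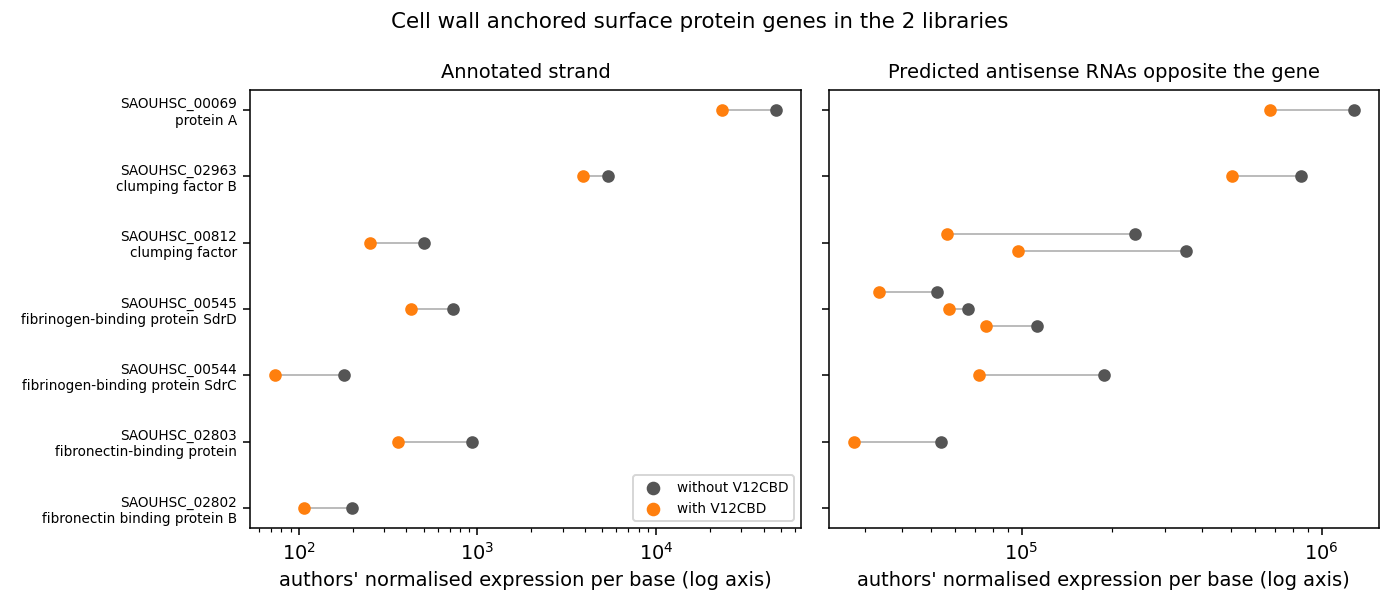
Normalised expression per base, on a log axis, of the 7 measured surface protein genes on the annotated strand (left) and of the 9 predicted antisense RNAs that lie opposite 6 of them (right). Grey points are the library without V12CBD and orange points the library with it; each line joins the values of 1 gene or RNA, and on the authors' scale all orange points lie left of their grey partners, while with equal totals over all features the RNA at 551422 to 551627 lies right of its partner.

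The predicted antisense RNAs, a comparison added after the data were seen, held far more reads, with a median of 2547 and 3124 each. Those opposite surface protein genes were also low. The RNAs opposite the clumping factor SAOUHSC_00812 had 46354 and 16122 reads (793100 to 794068, log2 ratio -2.08, interval -2.11 to -2.06) and 58991 and 23854 reads (795092 to 795922, -1.86, -1.89 to -1.84). The former had the lowest log2 ratio among 441 antisense RNAs. The RNA opposite protein A (73388 to 75091) had 438119 and 338973 reads (-0.93), that opposite SdrC 24617 and 13893 (-1.38), that opposite clumping factor B 169846 and 147101 (-0.77) and that opposite SAOUHSC_02803 2944 and 2217 (-0.97). The median antisense RNA stood at -0.29 on the authors' scale. Of 9 RNAs opposite 6 surface protein genes, 8 lay below that median, and their own median was -0.93 (random lists -0.62 to -0.04, percentile 0.06). The exception was 1 of 3 RNAs opposite SdrD (551422 to 551627), at -0.22. Opposite genes left out of the list, the RNA over SAOUHSC_02798 had 1352355 and 1439090 reads (-0.47). The 2 RNAs opposite SAOUHSC_02982 stood at -0.84 and -0.35.

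Ribosomal protein genes lay inside the random range on the annotated strand, and the antisense RNAs opposite them lay above it; the difference between the strands was not tested. On the annotated strand, 54 measured genes had a median log2 ratio of -0.19 (random lists -0.21 to 0.20, percentile 3.67), with 5 genes 2-fold higher and 8 lower. Among the lowest were rpsN (SAOUHSC_02499) with 7 and 1 reads (-3.04, -8.86 to -0.40) and rplK with 36 and 9 (-2.48, -3.80 to -1.48). The 24 antisense RNAs opposite ribosomal protein genes had a median of -0.07 (random lists -0.52 to -0.13, percentile 99.5), which is 0.22 above the median antisense RNA. Of these, 19 lay above the class median and none was 2-fold apart. The RNA opposite rplA and rplK had 80875 and 130944 reads (0.14), that opposite rplC and rplD 81004 and 136011 (0.19), that opposite rplU 5384 and 9586 (0.27), and that opposite rpsN and rpsH 8337 and 10864 (-0.18). Taking adjacent antisense RNAs as 1 unit left 11 units at 0.23 above the class median, inside the random range.

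**Figure D2:**
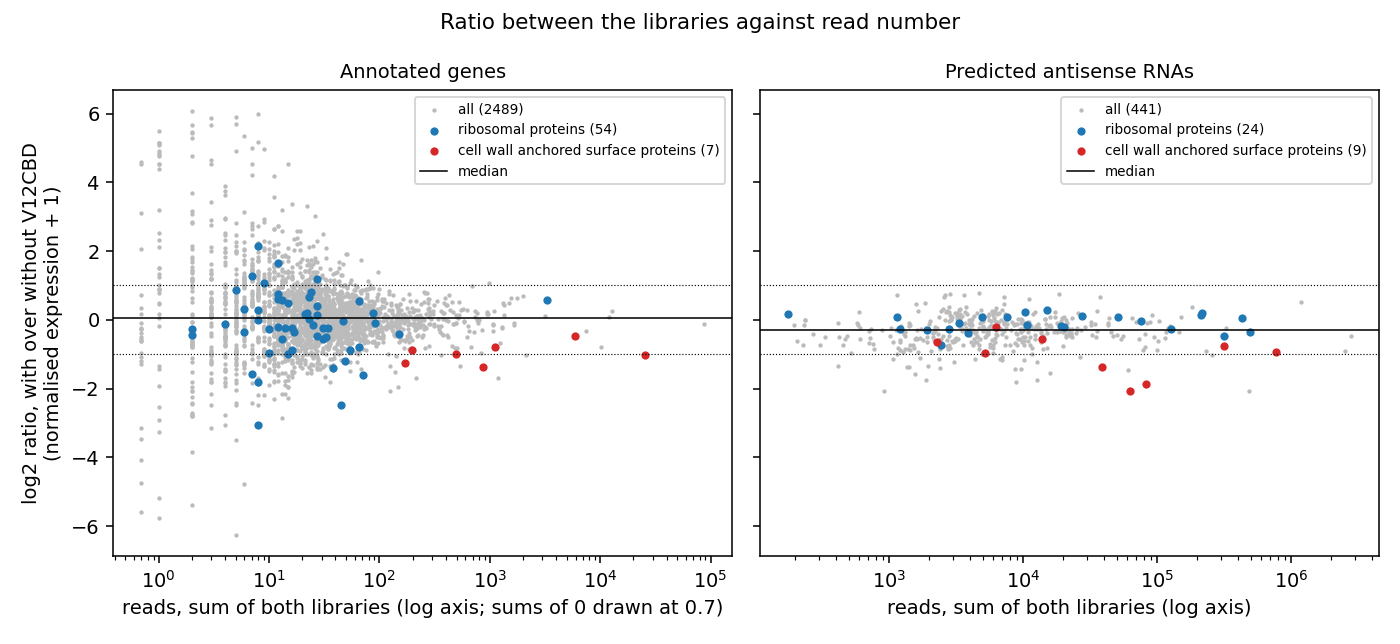
Log2 ratio of normalised expression (plus 1), with over without V12CBD, against the reads summed over both libraries on a log axis, for 2489 annotated genes (left) and 441 predicted antisense RNAs (right). Solid lines mark the class medians (0.05 and -0.29) and dotted lines a 2-fold difference; the spread of annotated genes is widest at low read numbers, and the 7 and 9 surface protein features are in red, with the ribosomal protein features in blue.

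By size alone, 348 of 2489 annotated genes were at least 2-fold higher with V12CBD and 236 lower. Most of these calls rested on few reads: in 100 simulated pairs of libraries without any difference, counting noise gave a mean of 211 higher and 186 lower. The split depended on the scaling. Equal totals over protein-coding genes gave 432 higher and 187 lower, and equal totals over all features gave 676 and 107. Leaving the 3 most read features out of the total gave 588 and 127, and RPKM gave 548 and 133. Among 619 genes with 50 reads or more over both libraries, a filter chosen after the data were seen, 10 were higher and 20 lower, where counting noise gave means of 2.08 and 1.10. After centring on their median they numbered 10 and 16. Equal totals over all features would move each ratio up by 0.46, and this split was not recounted there.

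The 20 deeper genes that were lower included 4 of the surface protein genes and 9 hypothetical proteins. Molybdenum cofactor biosynthesis protein A (SAOUHSC_02536) had 92 and 32 reads (-2.07, -2.71 to -1.49), and the high affinity proline permease SAOUHSC_02119 had 107 and 40 (-1.96, -2.54 to -1.44). The glycine betaine transporter SAOUHSC_01346, at the threshold, had 37 and 27 (-1.0, -1.78 to -0.26). The chaperone DnaJ (SAOUHSC_01682) had 92 and 47 reads (-1.52, -2.07 to -1.0), rplO 48 and 23 (-1.60, -2.40 to -0.87; the antisense RNA over it and 3 neighbours 153987 and 162994, -0.48), and the fibrinogen-binding protein-like SAOUHSC_01110 79 and 46 (-1.34, -1.90 to -0.80). The 10 that were higher included 7 hypothetical proteins, led by SAOUHSC_02592 with 7 and 44 reads (1.93, 0.93 to 3.49). Among these 7 was SAOUHSC_02167 with 11 and 57 reads (1.74, 0.87 to 2.90). The other 3 were ribose-5-phosphate isomerase A (SAOUHSC_02612) with 12 and 43 reads (1.16), the extracellular matrix and plasma binding protein SAOUHSC_00816 with 18 and 61 (1.14) and argininosuccinate synthase (SAOUHSC_00899) with 13 and 41 (1.08). Genes in this paragraph that the naming rule does not take were chosen after their values were seen.

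Among genes with a mean normalised expression of 50 or more, the 12 highest ratios belonged to genes with at most 17 reads in the library with V12CBD. Methionine sulfoxide reductase A (SAOUHSC_01432), which repairs oxidised methionine, had 2 and 16 reads (2.39, 0.35 to 5.61), and a ferredoxin (SAOUHSC_01504) had 1 and 8 (2.29, -0.46 to 7.91). Opposite methionine sulfoxide reductase A, an antisense RNA had 1597 and 1935 reads (-0.28, near the median antisense RNA). SAOUHSC_A02331, a hypothetical protein, was listed at 0 and 13 reads, with a normalised expression of 29 and 274, so its 0 stands for a fraction of a read. The 12 lowest included rpsN and rplK, a ribosomal-protein-serine acetyltransferase (SAOUHSC_00324) with 11 and 2 reads (-2.85, -6.23 to -0.82) and the stress regulator spxA with 10 and 3 (-2.15, -4.79 to -0.34). The antisense RNA opposite spxA had 4962 and 6490 reads (-0.17). In the authors' deposited table, 62 features had a q-value under 0.05, and 60 of them were protein-coding genes, 34 higher and 26 lower with V12CBD. In that table, 16 of the 62 had under 10 reads in both libraries, 16 were listed at 0 reads in 1 library and 1 at 0 in both. Of the surface protein genes, only SdrC was among the 62 (the authors' q-value 0.030). The authors' q-value was 0.947 for the clumping factor SAOUHSC_00812 and 0.690 for SAOUHSC_02803, and protein A was not among the 62 either. The only antisense RNA among them lay opposite hslU.

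Of 25 virulence and cell wall genes fixed beforehand, 3 were at least 2-fold higher and 4 lower. The genes rot, mgrA, cidA and tagO were also fixed beforehand. They could not be identified from names or products and are not among the 25. The balance depended on the scaling: 6 were higher and 2 lower with equal totals over protein-coding genes, and 8 and 1 with equal totals over all features. Equal upper quartiles put protein A and the clumping factor at -0.99, just short of 2-fold. Accessory regulator A (SAOUHSC_00620), a global DNA-binding regulator of virulence genes, had 8 and 35 reads (1.5, 0.44 to 2.89), while the antisense RNA opposite it had 11381 and 13703 (-0.29, the median of antisense RNAs). The histidine kinase SAOUHSC_02099, which senses cell wall damage, had 1 and 21 reads (3.30, 1.20 to 9.20), while its partner regulator VraR (SAOUHSC_02098) had 36 and 67 (0.34, -0.27 to 0.96). Delta-hemolysin (SAOUHSC_02260) had 1 and 7 reads (1.70, -0.71 to 7.74). The 4 lower genes were protein A, the clumping factor, the two-component response regulator SAOUHSC_00020, with 15 and 9 reads (-1.28, -2.67 to -0.01) and the capsular protein SAOUHSC_00114, with 4 and 1 (-1.74, -8.18 to 0.78). Accessory gene regulator protein A (SAOUHSC_02265), of the quorum-sensing system, had 59 and 71 reads (-0.29, -0.81 to 0.23), and the sensor SaeS (SAOUHSC_00714) 102 and 179 (0.25, -0.11 to 0.62). Alpha-hemolysin (SAOUHSC_01121) had 5 and 8 reads (0.15, -1.67 to 2.08), so a difference of 2-fold was not detectable at this depth. The bifunctional autolysin (SAOUHSC_00994), the main peptidoglycan hydrolase, had 84 and 134 reads (0.11, -0.29 to 0.53), and the antisense RNA opposite it had 1049 and 1087 (-0.51). The interval leaves out 2-fold either way for counting error on the authors' scale only. It does not exclude such a difference between conditions, and equal totals over all features would move the ratio up by 0.46.

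Of 40 gene lists with 3 or more measured members, 2 lay outside the range of random lists on the annotated strand, where 5% of lists, or 2, fall by chance. Besides the surface proteins, the histidine and tryptophan biosynthesis list had a median of 0.63 (random lists -0.40 to 0.62, percentile 97.6), with 6 of 16 members 2-fold higher and none lower. That list had no antisense RNA assigned to it. Its histidinol-phosphate aminotransferase SAOUHSC_03012 had 4 and 22 reads (1.71, 0.34 to 3.90), and hisZ had 1 and 9 (1.93, -0.24 to 8.07). This position was lost in 6 of the 8 alternatives other than rescaling, which moves a list and random lists alike. With genes at 0 reads in 1 library set at their bound, hisG with 0 and 4 reads among them, the median was 0.33 (percentile 76.5), and with adjacent genes as 1 unit the 3 units had a median of 0.09 (percentile 54.5).

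**Figure D3:**
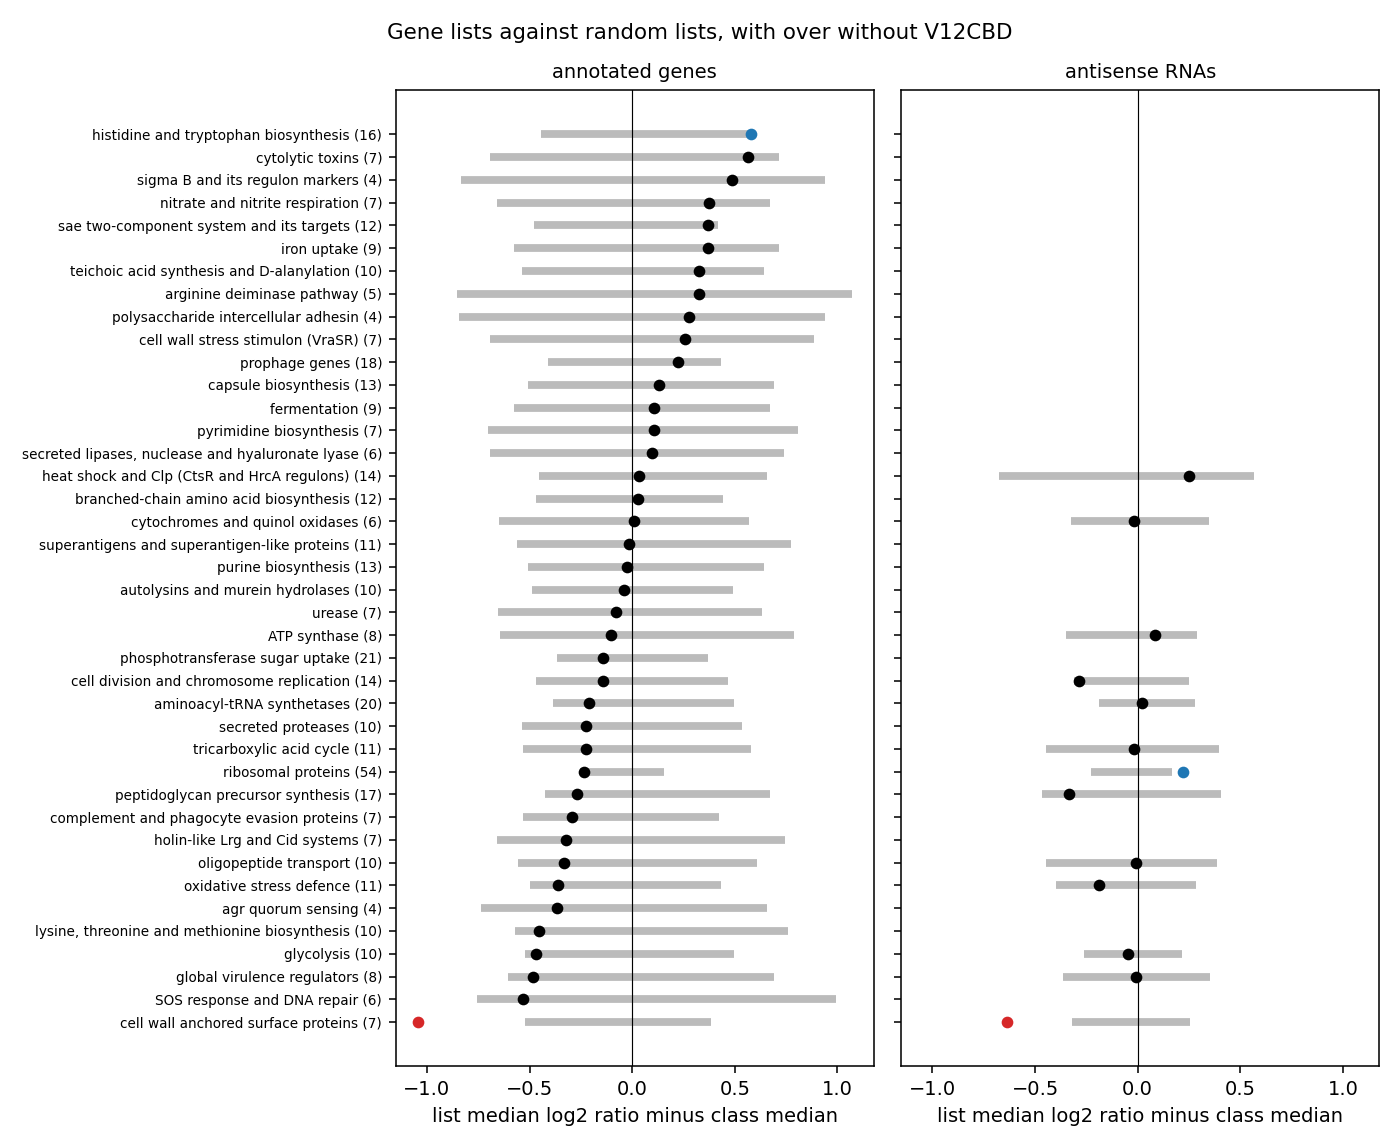
Median log2 ratio of each gene list minus the median of its class, with over without V12CBD, for 40 lists of annotated genes (left, measured members in parentheses) and 13 lists of predicted antisense RNAs (right). Grey bars span the central 95% of 10000 random lists of like expression; red points lie below the bar and blue points above it, with surface proteins lowest in both panels.

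On the annotated strand, genes for secreted toxins and their regulators lay inside the random range. No antisense RNA was assigned to the agr, cytolytic toxin or secreted protease list, and only 1 to the sae list. No antisense median was therefore available for these lists. The cytolytic toxin list rests on 57 reads without and 125 reads with V12CBD. Of 12 members of the sae list, the 2-component system and its targets, 9 lay above the median of genes, with a list median of 0.42 (percentile 96.2, random lists -0.43 to 0.46). The leukocidin S subunit SAOUHSC_02709 had 12 and 35 reads (0.98, 0.01 to 2.07). Among 7 cytolytic toxins (median 0.61, percentile 94.9), leukotoxin LukD (SAOUHSC_01954) had 2 and 15 reads (2.03, 0.24 to 5.52) and LukE (SAOUHSC_01955) 14 and 12 (-0.85, -2.02 to 0.44). Of 10 secreted proteases, 1 was 2-fold higher, SplE (SAOUHSC_01936) with 2 and 17 reads (2.58, 0.45 to 5.69), and 3 were lower, among them SplC (SAOUHSC_01939) with 7 and 3. The 4 measured agr genes had a median of -0.32 (percentile 17.1). In the list of 7 complement and phagocyte evasion proteins (median -0.25), which shares protein A with the surface proteins, staphylokinase (SAOUHSC_02171) had 76 and 78 reads (-0.53, -1.0 to -0.05). SAOUHSC_02167, with 11 and 57 reads (1.74), was drafted for this list and the sae list. It is in neither, because the annotation names it a hypothetical protein, so both lists leave out this higher gene.

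Cell wall gene lists were inside the range on the annotated strand too. The teichoic acid and capsule lists had no antisense RNA assigned, so they rest on that strand alone. None of 10 autolysins and murein hydrolases was 2-fold apart (median 0.01). Of 17 peptidoglycan precursor genes, 1 was 2-fold higher and 2 lower (median -0.22), the lower ones being mraY with 11 and 5 reads (-1.58, -3.57 to -0.05; opposite RNA 664 and 537, -0.86) and murG with 8 and 4. Teichoic acid genes had a median of 0.37 over 10 members, with 2 higher and none lower, and SAOUHSC_00223 had 1 and 11 reads (2.72, 0.12 to 8.33). The cell wall stress stimulon had 2 of 7 members higher (median 0.30, percentile 68.4). Of 13 capsule genes, 1 was higher and 2 lower, among them the glycosyltransferase SAOUHSC_00125 with 22 and 10 reads (-1.67, -2.94 to -0.56).

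In metabolism, 8 of 10 glycolysis genes lay below the median of genes and none was 2-fold apart (list median -0.42, percentile 4.11, random lists -0.48 to 0.54). The enolase gene eno had 35 and 26 reads (-0.95, -1.78 to -0.21). Among genes with 50 reads or more, the 4 remaining glycolysis genes had a median of -0.56 relative to all genes, below the random range (percentile 0.78). The 16 antisense RNAs opposite 10 glycolysis genes, with far more reads, lay inside their random range (relative median -0.05, percentile 32.8), and those opposite eno alone had 4341 and 5944 reads (-0.10) and 6883 and 9068 reads (-0.16). Of 13 purine biosynthesis genes, 1 was higher and 4 lower (median 0.02), and phosphoribosylamine--glycine ligase (SAOUHSC_01018) had 3 and 28 reads (2.5, 0.97 to 5.03). Of 7 nitrate and nitrite respiration genes, 1 was higher, the nitrate reductase subunit SAOUHSC_02679 with 1 and 12 reads (2.58, 0.27 to 8.44). The heat shock and Clp list had 2 of 14 members higher and 3 lower (median 0.08), and iron uptake 2 of 9 higher and 1 lower (median 0.42). No antisense RNA was assigned to the purine biosynthesis or iron uptake list. The global virulence regulators (8 members, percentile 5.38) and the lysine, threonine and methionine genes (10 members, 3 higher and 2 lower, percentile 5.75) lay low but inside the range.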

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

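The tests in this part were chosen after the results were seen. The exceptions, planned for annotated genes only, were the scalings by median of ratios, upper quartile, total over protein-coding genes and trimmed mean. Predicted RNAs that name no gene enter no comparison of the report, and 2 of the 28 had a share of reads at least 2 times as high with V12CBD, on counts far above the limit that a count of 0 allows. The RNA at 2027494 to 2027643 on the plus strand, between the hypothetical genes SAOUHSC_02157 and SAOUHSC_02158, had 2113 reads without and 5456 reads with V12CBD, a ratio of read shares of 2.41 (95% counting interval 2.29 to 2.54) and of 1.75 on the authors' scale. The RNA at 2446983 to 2448097 on the plus strand, between the hypothetical gene SAOUHSC_02663 and the transcriptional regulator SAOUHSC_02664, had 16857 and 36483 reads, a ratio of shares of 2.02 (1.99 to 2.06) and of 1.47 on the authors' scale.

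Surface protein genes, and the antisense RNAs opposite them, were lower with V12CBD. Reads on the strands of a gene cannot be fully separated here, so the strands are not 2 independent results. For the direction of the list median, the authors' scaling alone is argued against, since the median was -0.54 or lower under each of 5 other scalings. The planned scalings take their factor from annotated genes and moved the log2 scale by 0.15 at most, so they decide little. Equal totals over all features moved it by 0.46, and there no surface protein gene stayed 2-fold lower. A single decrease spread by shared reads over similar genes would spare other families, whereas all 3 families lay below the median of genes, the clumping factors and Sdr proteins least (-0.93). A later stage of growth in the culture with V12CBD cannot be told apart, because the rule asked for the same direction of ribosomal protein RNAs on both strands. They lay above their class on the antisense strand (0.22) and below it on the annotated strand (-0.24). The annotated-strand value lay inside its random range (percentile 3.67), so it decides little. The antisense value also came inside its range with adjacent RNAs as 1 unit. An effect of V12CBD on these genes stays open as a hypothesis, as does a chance difference between single cultures, because each group holds 1 library.

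Nearly all reads lay opposite annotated genes. A library without a strand mark would split the reads over a gene near evenly. Over 363 genes or gene groups, the median share on the annotated strand was instead 0.406% without and 0.454% with V12CBD. In either library, 0 of them had more reads on the annotated than on the antisense strand. Their median ratio of reads per base, antisense over annotated strand, was 980 without and 894 with V12CBD. These values cover only genes opposite a predicted antisense RNA. Antisense transcription beside messenger RNA on the annotated strand would leave ribosomal protein genes near the top of that strand, but their median percentile was at most 73.2. A candidate explanation that stays open is that the strand of messenger RNA was assigned in reverse: 72.7% of ribosomal protein genes lay opposite a predicted antisense RNA against 14.3% of protein-coding genes, 5.07 times as often. The strand that the library kit reads is not stated, and no other biological explanation was tested. If the reverse assignment held, the antisense values would be the deeper measure of these genes. The annotated-strand values given for genes would then come from the strand opposite their messenger RNA.

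Predicted antisense RNAs were lower more often than higher on the authors' scale (32 against 0 at 2-fold). The 3 most read features do not account for the scale, since leaving them out of the total still moved it by 0.35 on the log2 scale. The authors' scaling cannot be told apart from a decrease of most of these RNAs with V12CBD, since no RNA added in a known amount is described. Their scale lay close to one with equal upper quartiles of annotated genes (log2 shift 0.01), which hold few of the reads. As a share of all reads, these RNAs stood at 87.85% without and 87.51% with V12CBD. With equal totals over all features 50% of those 2-fold apart were lower (10 and 10), but these RNAs hold most of the reads, so this scaling nearly centres them. Lower against higher numbered 16 and 9 without the 3 most read features, 18 and 6 after centring on their median, and 24 and 0 with equal totals over protein-coding genes.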

How the results depend on the processing

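Tests chosen after the data were seen were those on equal totals over all features (with or without the 3 most read), 50 reads or more, counting intervals, genes at 0 reads at their bound, RPKM for the counts of genes, and all on antisense RNAs. No paired analysis was possible because each group holds 1 library, so no setting tests the spread between cultures.

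Surface protein genes stayed below the random range in all 15 settings, the main one included, of which 5 are rescalings that move the list and random lists alike and so decide nothing (relative median -1.05 to -0.98, percentile at most 0.195), and so did the antisense RNAs opposite them in all 6 (-0.65 to -0.55, percentile 0.02 to 0.62). Of 1701 values of 189 named genes under other settings, 1674 lay inside the main counting interval, and 27 outside, of which 16 came with RPKM and 7 with equal totals over all features. In 9 genes, 18 values changed sign, 9 of them with equal totals over all features, and none of these genes was 2-fold apart. The histidine and tryptophan list lost its position with a pseudocount of 5 (relative median 0.51), no expression floor (0.63), expression of 50 or more (0.76, 5 genes), without its most extreme member (0.48), with adjacent genes as 1 unit (0.049, 3 units) and with genes at 0 reads at their bound (0.28), each leaving 1 of the lists outside the range in place of 2. Fewer members or units widen the random range by construction; for the other settings the cause was not tested. The glycolysis list lay below the range with 50 reads or more (-0.56, 4 genes) and the antisense cell division list with any named gene counted (-0.32), where the antisense sigma B list, too small otherwise, lay above it (0.37, 3 RNAs), for which the cause was not tested, and the antisense ribosomal list came inside it with adjacent RNAs as 1 unit (0.23, fewer units).

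Genes higher and lower by the size rule numbered 676 and 107 with equal totals over all features, 588 and 127 without the 3 most read features, 548 and 133 with RPKM, 98 and 98 at expression of 50 or more, 643 and 484 at 1.5-fold, 116 and 45 at 4-fold, 19 and 18 with the authors' q-value under 0.01, 10 and 20 with 50 reads or more, and 83 and 75 where the counting interval leaves out equality. Antisense RNAs higher and lower numbered 6 and 18 after centring on their median, 10 and 10 with equal totals over all features, 9 and 16 without the 3 most read, 10 and 108 at 1.5-fold, and 3 were lower at 4-fold. Of the 25 fixed genes, 2 were lower with equal upper quartiles, 6 were higher and 2 lower with equal totals over protein-coding genes, and 8 higher and 1 lower with equal totals over all features. These shifts follow from the scale or the threshold itself; for RPKM the cause was not tested. Depth limits most genes: 1576 of 2767 had under 10 reads without V12CBD and 1195 with it.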

Other observations

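All tests in this part were chosen after the results were seen. The 441 antisense RNAs spanned log2 ratios of -2.08 to 0.78 (median -0.29). Opposite the cell division genes SAOUHSC_01149 and SAOUHSC_01150 (FtsZ, which forms the division ring), an RNA over both had 39480 and 21072 reads (-1.46), while 4 others opposite SAOUHSC_01149 lay from -0.77 to 0.08 and 1 opposite SAOUHSC_01150 at -0.74. Opposite the chaperone gene dnaK an RNA had 1040 and 519 (-1.56). Opposite gatA, of an amidotransferase that completes charged tRNA, 1 RNA had 6251 and 2618 reads (-1.81) and the other stood at -0.46, and opposite hslU, a protease subunit gene, 1 RNA had 673 and 238 reads (-2.05) and the other stood at -0.31. The RNA opposite SAOUHSC_01462 had 356693 and 124866 reads (-2.07), and another over it and SAOUHSC_01463 had 3032 and 4575 (0.04). Higher on the authors' scale were the RNA opposite the nitrate reductase alpha subunit SAOUHSC_02681, with 3455 and 7684 reads (0.60), and RNAs opposite the prophage tape measure gene SAOUHSC_02182 (0.78, with another at 0.24) and the phage-like gene SAOUHSC_02185 (0.75).

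Antisense RNAs opposite 1 gene were compared with each other. Among 61 genes with 2 or more such RNAs, the first 2 by position had a median absolute difference in log2 ratio of 0.36. Over all pairs of the 360 RNAs that name 1 gene it was 0.42. A range of 1 or more was seen in 6 genes, such as glucokinase (SAOUHSC_01646) at 0.67 and -1.0. Across 130 genes with 50 reads or more on the annotated strand, the log2 ratios of the strands had a Spearman rho of 0.24 and a Pearson r of 0.24, where genes are not independent replicates. rRNA genes held 0.0959% of reads without and 0.0726% with V12CBD, and tRNA genes 0.00791% and 0.00829%.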
